A study of Mus musculus with 9 samples.

How the data were processed

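Gene expression was measured in 9 samples of mouse regulatory T (Treg) cells, 5 wild-type and 4 lacking the Hippo kinases Mst1 and Mst2, with 1 whole-transcript Affymetrix microarray per sample. Per the labels' protocols, YFP-positive CD4 T cells that carried the CD45.2 allele were sorted from Rag1-deficient recipients reconstituted with a mixture of CD45.1 wild-type marrow and marrow of 1 of the donor genotypes. Donors carried YFP and Cre at the Foxp3 locus, alone or together with loxP-flanked Stk4 (which encodes Mst1) and Stk3 (which encodes Mst2). RNA was amplified and labelled with NuGEN kits, per the labels' protocols.

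The values are log2 expression values deposited by the authors, 1 per probe set and array. They were made with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects background, normalises arrays by quantiles and summarises probes on the log2 scale. The table held 41345 probe sets with values between 1.26 and 12.9, no missing value and no pair of identical columns. Sample medians lay between 3.99 and 4.08. As no scanner values were used, signal below background could not be separated from low signal, and the number of arrays limits the precision.

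Gene names came from the platform annotation given with the table. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none listed, and only those with 1 symbol were named. Entrez identifiers of 23328 of them matched the reference gene table (assembly GRCm38.p6), which was used only for names and for the order of genes. The genome build behind the array design is not given in the sources used here, so coordinates are not reported. Where a gene had more than 1 probe set (1082 genes), the probe set with the highest mean over the 9 samples stood for it, leaving 22180 genes. No probe set was paired with Stk3 in the annotation used here.

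The 5 wild-type samples were compared with the 4 null samples by limma 3.58.1 (lmFit and eBayes, in R 4.3.3), a two-sided moderated test with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. No filter on dim genes was applied. A second count required a fold of at least 1.5. On data simulated from the real means and spreads of the 22180 genes, the test recovered 46% of genes changed by 0.5 log2 units. It recovered 90% of those changed by 1 and 100% of those changed by 2, and 13 of its 176 calls were false. Simulated noise was independent between genes and of equal spread in both groups, unlike in the real samples. These shares therefore need not hold for the real data. Lists of genes were tested with camera in limma at a preset inter-gene correlation of 0.01, over the 30 lists with at least 5 measured members. Camera was repeated with an estimated correlation, and fry was run beside it. Adjusted p rose in the repeat even for the list of integrins and adhesion genes, whose estimated correlation (-0.015) lay below the preset. A call lost in the repeat therefore need not come from correlation between genes. For lists past the threshold, a score per sample (the mean over members of the log2 value minus the gene's mean over all 9 samples) was compared between groups by an exact two-sided permutation test over all 126 splits, whose smallest possible p is 0.0079.

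The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Stk4, Stk3 and Foxp3, the 14 genes with the largest positive and the 14 with the largest negative difference among those past the threshold whose groups did not overlap, and up to 4 passing members of each list with the smallest p (or 2 if none passed). Predicted gene models, antigen receptor segments, Xist and Y-linked genes were left out of these picks. Genes named outside this rule are marked as such where they appear.

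Alternatives were a block for the replicate number, a filter on dim genes, other ways to join probe sets, median centring, quantile normalisation between samples, other eBayes and weight settings, an estimated inter-gene correlation, and leaving out each array in turn. Alternatives added after seeing the data left out null arrays 2 and 4, adjusted for the level of Hspa1a and Hspa1b, or used only the 6 arrays with high values of both genes. Changed genes that neighbour each other in gene order were also subtracted from the count, without a new fit. Nothing in the labels names a sorting day, hybridisation batch or litter, and nothing says whether samples came from separate chimeras, so p-values measure the spread between these samples. Serial numbers in the sample titles place all wild-type samples before all null samples, with a number missing within the null run. What they mark is not stated, so an effect of that order cannot be told apart from genotype. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.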

Results

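Treg cells are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. Transcript levels were compared between wild-type Treg cells (n = 5) and Treg cells without Mst1 and Mst2 (n = 4), the kinases at the head of the Hippo pathway, all taken from mixed bone marrow chimeras. The comparison asks which transcripts depend on the 2 kinases in Treg cells, with particular attention, from the title of the study, to signalling through the interleukin-2 receptor and STAT5. Values are log2 RMA values, and each difference is null minus wild type. Null samples were more variable: their mean correlation with the other arrays of their group was between 0.968 and 0.975, against 0.984 to 0.986 in wild type. Each null array correlated slightly more with the wild-type arrays (means from 0.9693 to 0.9756) than with its own group. The first principal component of the 1000 most variable genes held 45.1% of their variance and parted the groups, from -15.2 to -8.54 in wild type and from 8.33 to 16.2 in null samples. The second, with 15.3%, set null array 2 (14.27) against null array 4 (-14.86).

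The targeted genes were examined first. Stk4 was 7.91 ± 0.10 (SD, n = 5) in wild type and 7.64 ± 0.15 (SD, n = 4) in null samples, a difference of -0.27 ± 0.084 (SE) that did not pass the test (limma adjusted p = 0.146), although each null value lay below each wild-type value. Its single probe set summarises probes along the whole transcript, and the exons removed by Cre are not given in the sources used here, so this level does not check the deletion. No level is given for Stk3, which had no named probe set. Foxp3 was 10.70 ± 0.049 (SD, n = 5) in wild type and 10.72 ± 0.092 (SD, n = 4) in null samples (difference 0.014, 95% interval from -0.13, limma adjusted p = 0.949).

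Null Treg cells had lower levels of genes that mark Treg cells, of integrins, and of genes that respond to interleukin-2. Effector Treg cell genes were also lower as a list at the preset correlation, but not with an estimated correlation (adjusted p = 0.0825 with an estimated correlation). These lists share members, and Itgae is in each of them, so their shifts are not independent results. Itgae, the CD103 integrin chain that binds E-cadherin, fell from 8.36 ± 0.25 (SD, n = 5) to 5.56 ± 0.41 (SD, n = 4), or 6.98-fold (limma adjusted p = 6.26e-05). Nrp1, a surface receptor of thymus-derived Treg cells, fell 4.06-fold, the inhibitory receptor Tigit 6.65-fold and the inhibitory cytokine gene Il10 3.36-fold. In the opposite direction, Pde3b, a cyclic nucleotide phosphodiesterase, rose to 4.91 ± 0.27 (SD, n = 4) and Dapl1, a gene of naive T cells, to 5.48 ± 0.83 (SD, n = 4). Their wild-type means (3.22 and 3.81) lay below the median of all probe sets, 4.047, where signal is not shown to exceed background, so no fold is given.

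Across all 22180 genes, 515 (2.32%) passed the limma test, 95 higher and 420 lower in null samples, and 288 of them changed at least 1.5-fold (53 higher, 235 lower). At an unadjusted p under 0.05 there were 3296 genes. In 503 of the 515 the groups did not overlap. Over all genes 6.2% had groups without overlap, where chance gives 1.59%. The share of changed genes that were higher was 18.4%, and 35.7% (170 higher genes) after quantile normalisation of the gene values. Leaving out any 1 of the wild-type arrays gave between 271 and 327 genes and leaving out null array 1 gave 280, while leaving out null array 2 gave 594. With a block for the replicate number 178 genes passed, 162 of them among the 515. Hspa1a and Hspa1b, heat shock genes singled out after their values were seen, were low in 3 arrays (2 wild-type, 1 null) and high in 6: limma called 468 genes with their level as a covariate, 432 of them among the 515, and 37 within the 6 arrays of high values, each of these among the 515, while the other 3 arrays hold 1 null sample and were not tested alone.

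**Figure D1:**
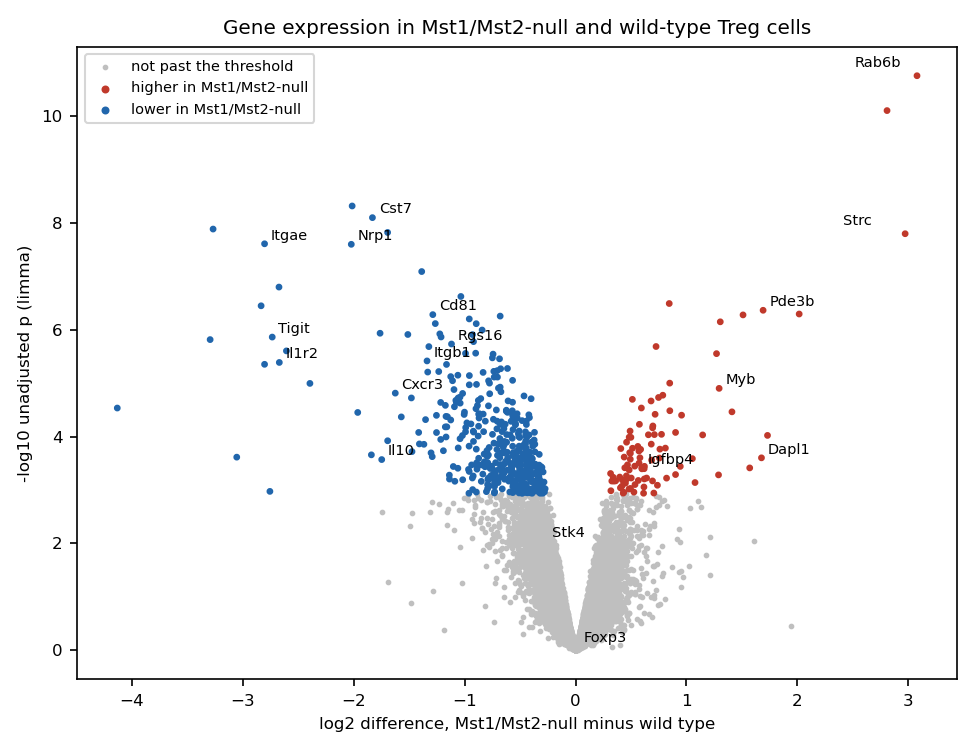
Each point is 1 gene, with the log2 difference between Mst1/Mst2-null (n = 4) and wild-type (n = 5) Treg cells on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Coloured points are the 515 genes with an adjusted p under 0.05, of which 420 were lower (blue) and 95 higher (red) in null cells, and Foxp3 and Stk4 lie among the grey points that did not pass.

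Of the 39 measured genes of the Treg cell signature, 17 fell, 0 rose and 22 did not pass over all genes, and 26 fell when adjusted over the list alone. The median difference was -0.62 (camera adjusted p = 6.09e-22, and adjusted p = 0.0068 with an estimated correlation). Itgae, Nrp1, Cd81 and Tigit had the smallest p, and Cd81, a tetraspanin, fell from 9.38 ± 0.19 (SD, n = 5) to 8.09 ± 0.20 (SD, n = 4). The list score differed by -0.71 between groups without overlap (exact permutation p = 0.0079, the smallest these groups allow). The list also contains Foxp3, which did not pass.

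Among 38 effector Treg cell genes, 11 fell and 1 rose over all genes, and 28 fell and 1 rose when adjusted over the list alone. The median was -0.78 (camera adjusted p = 7.36e-22, but adjusted p = 0.0825 with an estimated correlation, at which the list no longer passed). Besides Itgae and Tigit, Ebi3, a subunit of interleukin-35, fell 1.99-fold (limma adjusted p = 0.0016), while its second probe set did not pass (difference -0.55, limma adjusted p = 0.103). The rise was in Myb, a transcription factor required for effector Treg cells, from 6.85 ± 0.15 (SD, n = 5) to 8.14 ± 0.40 (SD, n = 4), and its second probe set also rose (difference 1.52). Effector list scores did not overlap between groups (difference -0.83, exact permutation p = 0.0079).

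Genes responsive to interleukin-2 and STAT5 were lower as a group. Of 62 measured, 17 fell and 1 rose over all genes, and 28 fell and 3 rose when adjusted over the list alone (median -0.26, camera adjusted p = 5.40e-11, and adjusted p = 0.0238 with an estimated correlation). Cst7, which encodes a protease inhibitor, fell from 8.90 ± 0.13 (SD, n = 5) to 7.07 ± 0.22 (SD, n = 4), with Itgae, Nrp1 and Cd81 next by p. The gene that rose, named after its value was seen, was the cytokine gene Osm (difference 0.40). Many members also belong to the Treg cell signature. Components of the receptor and of the JAK-STAT pathway did not pass as a list (16 measured, median 0.012, camera adjusted p = 0.362). Its 1 change over all genes (2 fell over the list alone) was in Il2rb, the receptor's beta chain, which fell by 0.33 on the log2 scale (limma adjusted p = 0.0305), while Il2ra (difference 0.056) and Cish (difference -0.26), named after their values were seen, did not pass. The list score of responsive genes differed by -0.42 (exact permutation p = 0.0079).

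Integrins and adhesion genes fell in 7 of 26 cases over all genes and 10 when adjusted over the list alone (median -0.13, mean -0.36, camera adjusted p = 1.58e-07, and adjusted p = 0.0068 with an estimated correlation). Itgb1, the beta-1 integrin chain, fell 2.53-fold, Itgb8, which takes part in activating TGF-beta, 2.25-fold and Icam1, an adhesion ligand, 1.68-fold. None rose. The scores of this list lay apart by -0.36 (exact permutation p = 0.0079).

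Resting and lymphoid homing genes moved the other way. Dapl1 and Igfbp4 rose and 0 fell of 20 over all genes, and 12 rose when adjusted over the list alone (median 0.40, camera adjusted p = 6.57e-09, but adjusted p = 0.182 with an estimated correlation). Igfbp4 was 6.68 ± 0.19 (SD, n = 5) in wild type and 7.28 ± 0.19 (SD, n = 4) in null samples. Markers of conventional naive CD4 T cells, a list that shares members with the previous one, rose in 3 of 15 cases (Pde3b, Dapl1 and Igfbp4) and in 8 when adjusted over the list alone (median 0.43, camera adjusted p = 1.75e-07, but adjusted p = 0.053 with an estimated correlation). Both lists had scores without overlap between groups (differences 0.39 and 0.47, exact permutation p = 0.0079 for each).

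**Figure D2:**
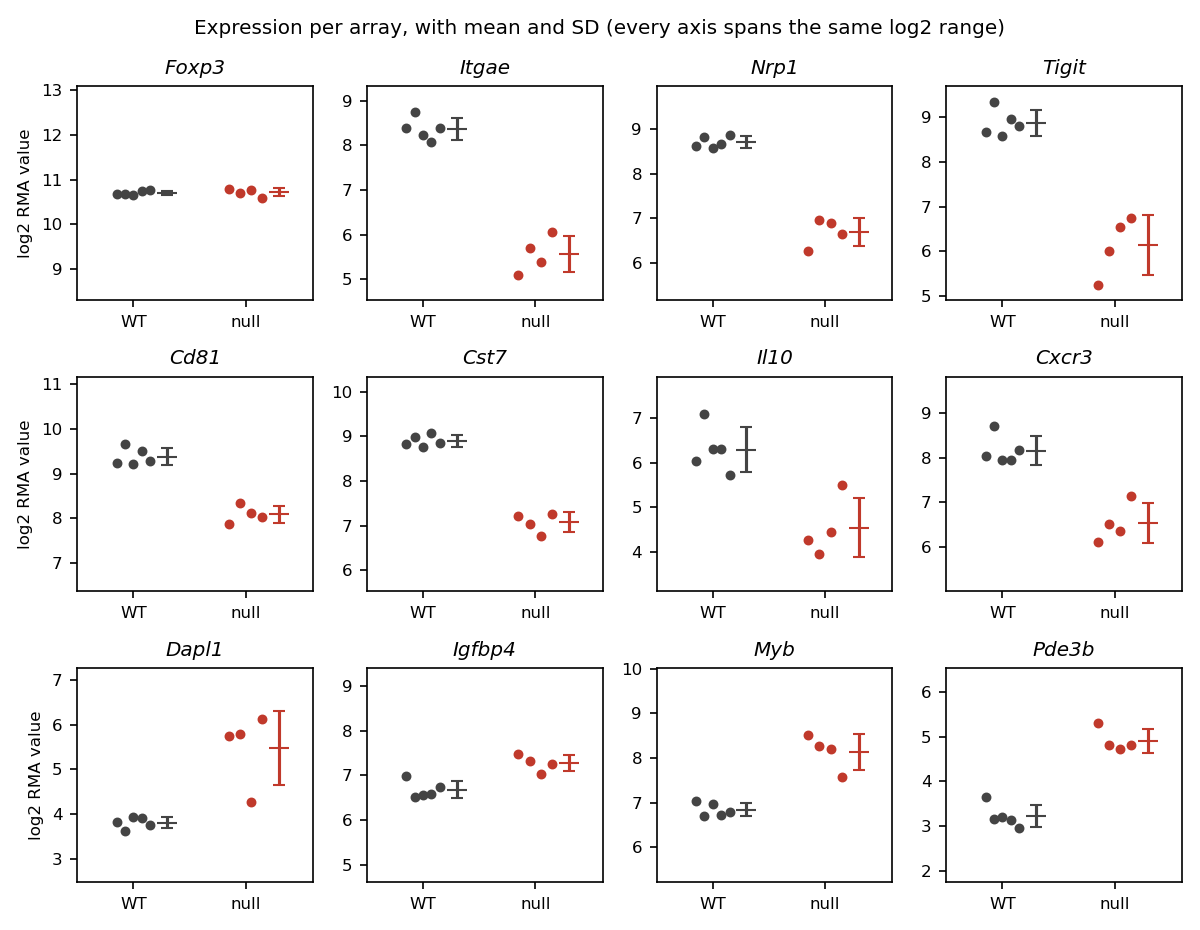
Each panel shows the log2 RMA value of 1 gene in every array (points), with the group mean and SD beside it, for wild-type (n = 5, grey) and Mst1/Mst2-null (n = 4, red) Treg cells. The vertical axes start at different levels but cover the same range, Foxp3 is near 10.7 in both groups, and in the other genes shown the groups do not overlap.

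Metabolic and cytoskeletal lists were lower at the preset correlation and not with an estimated one. The glycolysis and actin lists also lost their call with the filter on dim genes, and the actin list after quantile normalisation. Glycolysis and HIF-1 response genes fell in 2 of 23 cases (Hif1a, the oxygen-regulated transcription factor, 1.48-fold, and the glycolytic enzyme gene Pgk1, 1.53-fold), with 6 lower and 1 higher when adjusted over the list alone (median -0.14, camera adjusted p = 0.0020, but adjusted p = 0.33 with an estimated correlation). In cholesterol synthesis, 2 of 24 genes fell, the fatty acid synthase Fasn and the mevalonate pathway enzyme Pmvk, and 5 when adjusted over the list alone (median -0.17, camera adjusted p = 0.00067, but adjusted p = 0.33 with an estimated correlation, and 0.0566 within the 6 arrays of high Hspa1a and Hspa1b). Oxidative phosphorylation genes fell in 3 of 52 cases (Atp5a1, Sdha and Ndufa8) and in 4 when adjusted over the list alone (median -0.11, camera adjusted p = 6.27e-05, but adjusted p = 0.54 with an estimated correlation). Among actin cytoskeleton and Rac signalling genes only the scaffold gene Iqgap1 fell of 38, and 2 fell when adjusted over the list alone (median -0.089, camera adjusted p = 0.0017, but adjusted p = 0.33 with an estimated correlation). Exact permutation p-values of the list scores were 0.0079 for glycolysis, 0.0159 for actin, 0.0794 for cholesterol synthesis and 0.0873 for oxidative phosphorylation. By fry, which asks only whether a list's genes move on balance one way and compares with no other genes, adjusted p was 0.0328 for glycolysis and for actin, 0.054 for cholesterol synthesis, 0.161 for oxidative phosphorylation, 0.0037 for effector genes and for naive CD4 markers, 0.023 for resting genes, 0.404 for B cell markers, 5.36e-05 for the Treg cell signature, 0.000175 for genes responsive to interleukin-2 and 7.68e-06 for integrins.

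**Figure D3:**
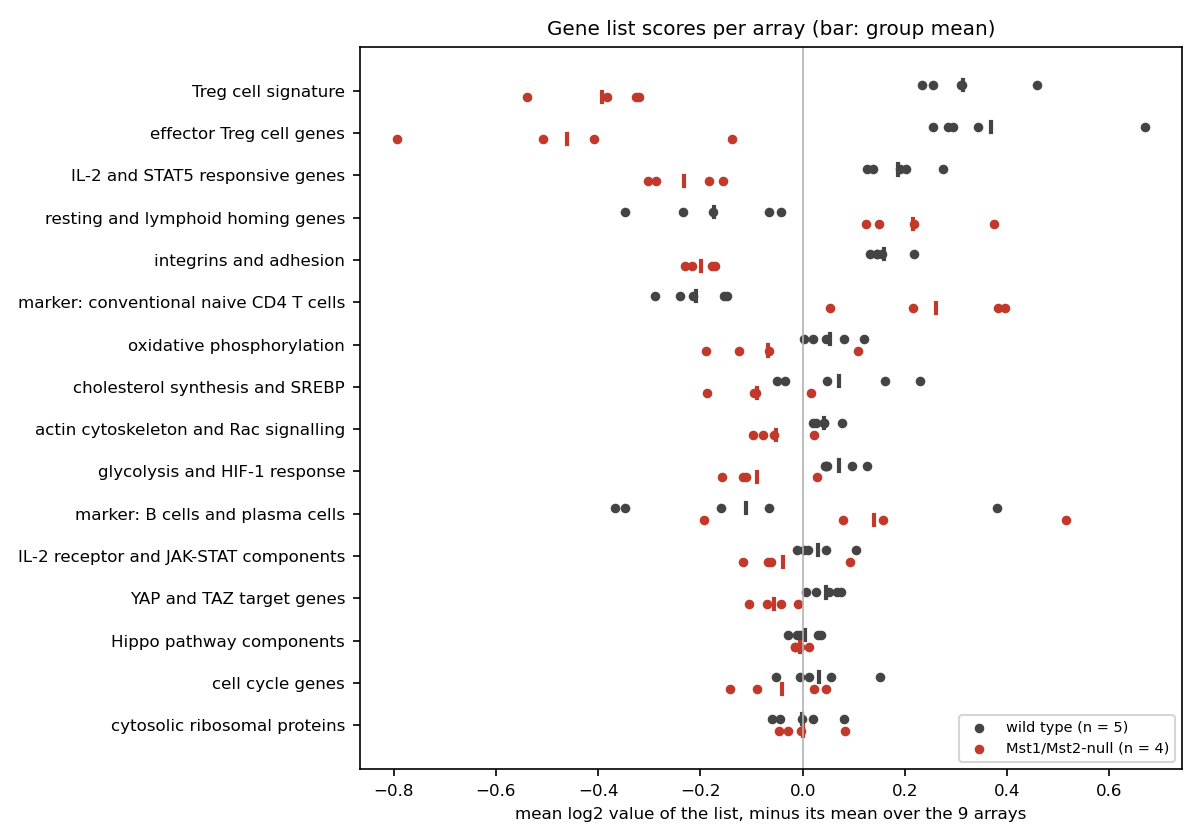
Points are list scores of single arrays (horizontal axis, log2 units relative to the mean of all 9 arrays) and bars are group means, for wild type (grey, n = 5) and null (red, n = 4). The 11 lists past the camera threshold stand at the top and 5 lists that did not pass below, and the Treg cell signature, effector, interleukin-2, resting, integrin, naive and glycolysis lists show groups without overlap, as do the YAP and TAZ targets among those that did not pass.

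Markers of other cell types were read in the same arrays as all groups above. The list of B cell and plasma cell markers was higher in null samples (18 measured, 0 passed over all genes or when adjusted over the list alone, median 0.23, camera adjusted p = 0.0080, but adjusted p = 0.55 with an estimated correlation). Its scores overlapped between groups (exact permutation p = 0.238) and were highest in null array 4 (0.516) and wild-type array 1 (0.381). Without null array 4 this list no longer passed (camera adjusted p = 0.313), nor without wild-type array 5 (0.0766). Cd79a, part of the B cell receptor, had a difference of 0.61 that did not pass. Myeloid markers (camera adjusted p = 0.0686) had their highest score in null array 4 (0.585), and Ctss, a cathepsin, was the 1 of 28 that passed, falling by 0.42 on the log2 scale (1 rose and 2 fell over the list alone). CD8 T cell markers (adjusted p = 0.362) included 2 falls, in Cxcr3 and the granule gene Nkg7 (1 rose and 3 fell over the list alone), and markers of NK cells (0.263), thymocytes (0.358) and erythroid cells (0.785) had no member that passed over all genes, while 1 thymocyte marker rose over the list alone.

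No shift passed in the remaining lists. Members are named here by the test over all genes, and counts adjusted over the list alone are given where they differ from it. For Hippo pathway components the camera adjusted p was 0.944 and 1 of 27 changed, the kinase gene Stk38, which rose by 0.50 on the log2 scale (1 rose and 1 fell over the list alone). YAP and TAZ target genes (camera adjusted p = 0.740) contained 2 falls, in the receptor kinase gene Axl and in Nt5e, the ecto-nucleotidase CD73. List scores of YAP and TAZ targets (difference -0.10) and of CD8 T cell markers (-0.32) did not overlap between groups either (exact permutation p = 0.0079 for each), a test planned only for lists past the camera threshold. Their medians (0.030 and 0.059) had the opposite sign, as did the median of the receptor and JAK-STAT list (0.012) against its mean (-0.069), that of unfolded protein and heat shock genes (0.029) against its mean (-0.0049), and that of ribosomal proteins (-0.010) against its mean (0.0018). T cell receptor and costimulation genes (camera adjusted p = 0.0603) contained 3 falls, in Malt1, Nfatc1 and Icos (6 fell over the list alone). In the chemokine receptor list (0.158) Cxcr3 fell 3.08-fold and Cxcr5 1.73-fold (1 rose and 3 fell over the list alone), and Cxcr5 also fell among helper T cell effector genes (0.0515), of which 6 fell over the list alone. FOXO targets (0.161) had 1 rise, Trib2, and 1 fall, Sod2, but 7 rose and 3 fell over the list alone. Unfolded protein and heat shock genes (0.362) had falls of the chaperone genes Canx and Calr (1 rose and 5 fell over the list alone). The pro-apoptotic gene Bid fell in the BCL-2 list (0.253), and Gbp7 fell among interferon response genes (0.748), of which 3 rose and 3 fell over the list alone. Cell cycle genes (0.161), immediate early genes (0.0963), MYC and ribosome biogenesis genes (0.882) and ribosomal proteins (0.944) had no member past the threshold over all genes, and only the MYC list had any over the list alone (1 rose and 1 fell).

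Among other single genes, Rab6b, a Golgi-associated GTPase gene, rose from 5.08 ± 0.15 (SD, n = 5) to 8.16 ± 0.17 (SD, n = 4), and Strc, known for its role in inner ear hair cells, rose to 6.39 ± 0.38 (SD, n = 4) from a wild-type mean of 3.42. The means of Strc and Mir181b-2 in wild type and of Trim30d, Trim12a and Naip2 in null samples lay below the median of all probe sets, so the sizes of their differences are not exact. Both probe sets of Rab6b rose, as both of Trim34a fell. The second probe sets of Kcnmb4 (difference 0.44, limma adjusted p = 0.218), Gprasp2 (-0.98, 0.0524), Hif1a (-0.28, 0.201) and Ndufa8 (-0.19, 0.443) did not pass. Scmh1, a Polycomb group gene, rose 2.85-fold and the potassium channel subunit gene Kcnmb4 2.41-fold, and Dzip1, Uchl3, Ms4a4c and the microRNA gene Mir181b-2 also rose. Il1r2, the decoy receptor for interleukin-1, fell 6.36-fold, Gprasp2 3.90-fold and the myosin gene Myo1f 3.58-fold. Large differences in Trim30d, Trim12a, Trim34a, Naip2 and Naip5 (lower) and in Gbp8, Ifi204 and Ifi214 (higher) are uncertain. These genes have near-identical relatives to which probes can bind, so which relative changed, if any, is not known. Such binding was not tested, and differences between mouse lines in linked DNA stay open as well. The same holds for Rps13, lower by 3.29 log2 units, which has many processed copies. Of 28 genes named for the size of their change, 14 had a changed gene among the 5 nearest on either side. For 9 of these it was from another symbol family: Il1r2, Itgae, Kcnmb4, Naip2, Naip5, Nrp1, Rab6b, Rps13 and Uchl3. Such a neighbour from another family was found for 137 of the 511 changed genes with a place in the gene order. Random sets matched on expression gave a median of 116.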

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

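Of the tests in this part, those on cell admixture, on the share of effector cells, on B cells, on the chromosomes of neighbouring genes, on neighbours of the same family and on splits with an estimated correlation were chosen after the results were seen, as were the interval around the share of changed genes near Stk4 and Stk3 and all uses of Hspa1a and Hspa1b.

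The number of changed genes exceeded what other groupings of the samples gave. The real grouping gave 515 genes, the highest other count was 0, and 1 of 100 splits of the 9 samples, the real one itself, reached the real count. A random grouping is thus unlikely to give that count. Every other split mixed wild-type and null samples, which widens the spread within its groups and lowers its count. For the 11 gene lists past the camera threshold chance cannot be excluded, because 20 of 100 splits gave as many and the highest other split gave 16. With an estimated correlation the real grouping gave 3 lists, the highest other gave 1, and 1 of 100 splits, again the real one, reached 3. A random grouping is thus unlikely to give 3 lists, with the same limit.

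Null Treg cells had lower effector genes (median -0.7827) and higher resting genes, 2 list shifts that did not pass with an estimated correlation (adjusted p = 0.0825 and 0.1824 with an estimated correlation). Foxp3-negative conventional T cells in the sort would lower Foxp3 as well, but the lower 95% bound of its difference was -0.1253, well above the effector median. This argues against such admixture as the whole cause of the lower effector genes. The bound leaves room for a small admixture and was not compared with the rise of resting genes or of naive CD4 markers (median 0.4267). Admixture stays open for that rise. With the level of Hspa1a and Hspa1b as a covariate the effector median was -0.7801. Arrays low for both lay in both groups (2 wild-type, 1 null), so the covariate could hardly move it. Within the 6 high arrays effector scores still did not overlap (0.2551 to 0.3432 in wild type, -0.5077 to -0.1373 in null samples). This argues against the difference between arrays that these genes mark as the whole cause. A smaller share of effector cells among Foxp3-positive cells and a lower level per cell cannot be told apart in bulk RNA. No test was run that separates them, and the loss of Mst1 and Mst2, the difference the design names, stays open as the biological explanation.

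The B cell marker list was higher in null samples, and 15 of 18 markers (83.3%) had a positive difference. This share restates the list's shift, the markers move together and the list scores overlapped between groups (exact permutation p = 0.238), so it does not decide whether B cells were in the null sorts, which the gate on CD4 and YFP should remove. Ighm, the marker with the highest signal and named after its values were seen, was 10.28 ± 0.16 (SD, n = 5) in wild type and 10.11 ± 0.52 (SD, n = 4) in null samples, and the list lost its call without null array 4 (camera adjusted p = 0.313), without wild-type array 5 (0.0766) or with an estimated correlation (adjusted p = 0.5525). A change of these genes within Treg cells was not tested.

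Some changed genes lay next to each other in gene order: with 5 genes on each side, 137 had a changed neighbour from another symbol family, against a median of 116 in 10000 random sets matched on expression, whose central 95% ended at 140, so differences between mouse lines in linked DNA stay open, also for the 9 named genes of largest change that have such a neighbour, Itgae and Nrp1 among them. Of the genes with a changed neighbour 90.7% had one from another family, which met the bound of over 50% set beforehand against probe sets shared between paralogs, but random sets gave a median of 97.8%, so that bound excludes nothing. With 14 changed genes next to one of their own family, against a median of 2 and a central 95% up to 8 in random sets, shared probe sets stay open. Differences between mouse lines in linked DNA stay open for these genes too. Linkage to DNA flanking Stk4 and Stk3 cannot explain the 127 of the 137 genes on chromosomes that carry neither gene. That count was not set against the share of all genes on those chromosomes. Effects of DNA flanking Stk4 and Stk3 on genes elsewhere were not tested. Near both loci 2 of 100 genes changed (percentile 36.8 among all windows, no higher than the median window); this met the bound set beforehand against flanking DNA, but with an upper 95% limit of 7.04% it could not be told apart from 6%, where the central 95% of windows ended.

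Single samples far from the rest of their group appeared in 11 of 176 groups tested, where chance gives about 1 in 20, or 8.8. In null array 1 Calr was low (7.56) and Pde3b (5.309) and Themis (8.063) were high, and in null array 3 Ifi204 was low (5.153). In wild-type array 1 Cd79a was high (5.97) and Klf1 low (2.873), in array 2 Pmvk was low (6.237), and in array 3 Nkg7 was low (7.663) and Stk4 high (8.093). Wild-type array 2 also had high scores for the effector list (0.669) and for integrins and adhesion (0.218).

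Probe sets without a single named gene also carried signal. When all 41345 were tested with limma, 529 passed, of which 219 had no single gene (110 higher and 109 lower in null samples).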

How the results depend on the processing

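The settings that left out null arrays 2 and 4, left out neighbouring genes, or used Hspa1a and Hspa1b were added after seeing the data. Where no cause is given below, the cause was not tested. Signal over background was not used, and the number of samples limits the precision of the counts.

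Of 59 named genes that passed, 53 also passed in each planned setting other than the replicate block and the left-out arrays, 38 passed whichever array was left out, and none changed direction there. Pde3b is among the 53, although the filter on dim genes removed it. With the replicate block 30 passed. Counts of changed genes stayed within 1.5 times the main 515 in the settings of filter, probe sets, centring, quantile normalisation, eBayes and weights. So did the count with the Hspa1a and Hspa1b covariate (468). Taking the 137 neighbouring genes away from the 515 left 378, a subtraction without a new fit that tests nothing. After quantile normalisation 170 were higher. Same-numbered arrays did not deviate together (correlations from -0.115 to 0.042). This gives no sign that the numbers pair the samples, but does not exclude it. With the replicate block on 8 arrays, 178 genes passed (30 higher, 148 lower, 162 of them among the 515), and 170 changed at least 1.5-fold (28 higher, 142 lower).

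Leaving out 1 array gave 271 to 594 genes (45 to 122 higher, 226 to 494 lower) and 185 to 349 at 1.5-fold (33 to 67 higher, 151 to 282 lower). The lowest counts came without wild-type array 4 (271), null array 1 (280), wild-type arrays 2 (282), 5 (314), 3 (322) and 1 (327). Within the 6 arrays of high Hspa1a and Hspa1b, 37 genes passed (11 higher, 26 lower), all at least 1.5-fold. Without null arrays 2 and 4, 735 genes passed (149 higher, 586 lower, 345 of them among the 515), and 81 of the higher ones changed at least 1.5-fold. Foxp3, which never passed, changed sign without null array 1 (-0.013), without null array 3 (-0.0063) and within the 6 arrays (-0.034), and ranged from -0.013 to 0.055 over single left-out arrays.

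With an estimated correlation 3 lists passed, and adjusted p rose to 0.0825 for effector genes, 0.1824 for resting genes, 0.05304 for naive CD4 markers, 0.54 for oxidative phosphorylation, 0.3295 for cholesterol synthesis, for actin and for glycolysis, and 0.5525 for B cell markers. With the dim filter, adjusted p was 0.1142 for actin and 0.08463 for glycolysis, and with quantile normalisation 0.1736 for actin. Cholesterol synthesis reached 0.05661 within the 6 arrays. B cell markers reached 0.5427 without null arrays 2 and 4, and ranged from 4.163e-06 to 0.3133 over single left-out arrays, with no call without null array 4 or wild-type array 5. Leaving out 1 array gave 12 to 14 lists.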

Other observations

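The genes in this part were chosen after their values were seen. Within each group some genes differed between arrays by far more than the groups differed. The inducible heat shock genes Hspa1a and Hspa1b were low in wild-type arrays 1 and 2 (Hspa1a 5.18 and 2.80) and in null array 1 (3.18). In the other 6 arrays Hspa1a lay between 8.11 and 9.93 and Hspa1b between 9.01 and 10.48. Of the 22 other measured members of the unfolded protein and heat shock list, 5 had the same 3 arrays as their lowest (Atf3, Dnajb1, Hspa8, Hspd1 and Hsph1), where chance gives 1.19% of genes. Dnajb1, a co-chaperone gene, was 6.28, 6.21 and 6.70 in these arrays and at least 7.25 in the rest.

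Kcnma1, a potassium channel gene, was 10.58 in wild-type array 4, 9.05 in null array 3 and 11.94 in null array 4, against 3.25 to 5.14 in the others. Bpifa2, a gene of salivary secretions, was 8.26 and 8.31 in wild-type arrays 1 and 3 and 9.10 in null array 2, and was 3.11 in null array 1. The calprotectin genes S100a8 and S100a9, abundant in neutrophils, were highest in null array 4 (8.90 and 8.41), and S100a8 was 2.91 in null array 2.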
